A study of Apostichopus japonicus with 3 samples.

How the data were processed

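Messenger RNA from the sea cucumber Apostichopus japonicus was measured by short-read sequencing. It holds 3 libraries: animals kept in natural light of about 100 lux (control), animals kept for 2 h in a fully dark, covered tank (dark), and animals kept for 2 h under strong light of about 2000 lux (light). Each group has 1 library. The number of animals behind a library is not given in the sources used here. The tissue label, the extraction protocol and the series title name the body wall, while the source label of each sample names the intestine; the text below follows the body wall and reports a list of digestive genes beside it.

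Per the labels' protocols, total RNA was treated with DNase, messenger RNA was enriched on oligo(dT) beads, fragmented, and copied into double-stranded cDNA from random hexamer primers before adaptor ligation and PCR. This protocol records no strand marking and no molecular identifiers, so reads are not independent molecules and every interval below covers counting error only. Per the submitters' processing notes, CASAVA 1.5 was used. The assembler, the aligner and the filters on reads are not given in the sources used here.

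The features are isotigs, transcripts assembled from reads. Several isotigs can stand for splice forms, alleles or fragments of 1 gene, and reads can be divided between them. Per the file headers, each library has a table of counts of uniquely assigned reads per isotig, the isotig length in bases, the percent of the isotig covered by reads, and RPKM (reads scaled by isotig length and by the library total). In each table the deposited counts summed to the total in the header, and the deposited RPKM equalled reads divided by length and by that total. Isotigs without reads in a library are left out of its table and were taken as 0 counts. Isotigs with 1 read were covered over 49 bases, which was taken as the read length. The deposited coverage percent was used only in a check for RNA breakdown, which left that question open. Names come from the KEGG orthology and protein database hits in the tables: 7377 of the 21290 isotigs had a name. Among the 7441 isotigs with a KEGG hit, 13.5% had a best hit with an E-value above 1e-10, and such names are uncertain. Among the isotigs named below this holds for isotig13012, isotig21096, isotig29479, isotig22036, isotig25684 and isotig08827, and for others. It holds for 4 of the 12 highest and 4 of the 12 lowest named isotigs in light vs control. The reference table of gene symbols shares no identifiers with the isotigs and was not used here, and no genome positions are given.

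Log2 ratios were computed from the deposited RPKM plus a pseudocount of 0.5, for the 18225 isotigs with a mean of at least 1 RPKM over the 3 libraries. The ratios of low isotigs are understated on this scale. Isotigs were counted when they were at least 2-fold apart. With 1 library per group no test between conditions is possible and no p-value is given; every ratio compares 2 libraries. The ratio of reads per library total of each named isotig has an exact conditional binomial (Clopper-Pearson) 95% interval, called the counting interval below. Where an isotig had 0 reads in a library, no ratio can be formed, and the smallest fold in its counting interval is given after the words at least. Libraries without any change were simulated 100 times by Poisson draws from the pooled counts. Each gene list has the median of its log2 ratios with an order-statistic 95% interval. It also has the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. These random lists were drawn from all tested isotigs, 11796 of them without a name, while every list member has a name. Taking 3 counts in place of 0 reads moved a list median by at most 0.11 on the log2 scale in any comparison.

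The comparisons, the filter, the fold limit, the 15 gene lists and the rule for named isotigs were fixed before the data were examined. The rule took the 12 highest and 12 lowest log2 ratios among named isotigs with a mean of at least 5 RPKM for light vs control and for dark vs control, the 3 highest and 3 lowest for light vs dark, and members of the lists that were at least 2-fold apart. The name patterns of the lists were adapted to the KEGG wording after the annotation and the ratios had been seen; the patterns as first written were run as an alternative chosen after seeing the data. Summing RPKM over the isotigs of one KEGG orthology and filtering on control and light alone were also chosen after seeing the data. The alternatives fixed beforehand were median-of-ratios size factors, TMM factors, totals without the 20 most abundant isotigs, pseudocounts of 0.1 and 1 RPKM, other filters, fold limits of 1.5 and 4, and a minimum isotig length.

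The counting, interval and list steps were tested on simulated data with the 18225 tested isotigs, in which 50 isotigs each were set 4-fold higher, 4-fold lower, 1.5-fold higher and 1.5-fold lower. In the simulated light vs control comparison 94.0% of the 4-fold higher and 80.0% of the 4-fold lower ones were at least 2-fold apart, as were 12.1% of the unchanged isotigs, and 96.8% of the intervals held the true ratio. In the simulated dark vs control comparison the shares were 96.0%, 84.0%, 12.2% and 97.0%. Of the isotigs set 1.5-fold higher and 1.5-fold lower, 14% and 24% were counted in light vs control. In dark vs control 14% and 18% were counted, so changes of this size were mostly missed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only.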

Results

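Gene expression in the body wall of Apostichopus japonicus, a sea cucumber, was measured in 3 libraries, 1 each from animals in natural light, animals after 2 h in the dark and animals after 2 h under strong light. The control, dark and light libraries listed 19435, 18948 and 19664 isotigs, of which 17337 had reads in all 3 libraries. The tested isotigs had a median of 18 reads averaged over the libraries, so most single ratios are imprecise. No group has a replicate, so none of the differences below could be set against the spread between animals.

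The series title names strong lighting and darkness as the conditions of interest, and the first comparison asks which transcripts differed after strong light. The light library stood close to the control library. Ribosomal protein transcripts, the abundant fibrillar collagens and the abundant chaperones were at similar levels, and the median log2 ratio over all tested isotigs was 0.00. Among well-counted isotigs, a transcript named lysosomal-associated membrane protein (isotig13012) had a log2 ratio of 1.32, with 369 reads in control and 968 after strong light. A transcript named early growth response protein 1 (isotig13219), an immediate-early transcription factor, was 2.83-fold lower (95% counting interval 2.22 to 3.64). The latter was also lower in the dark, 4.34-fold (3.28 to 5.83). These 2 were singled out after their values were seen.

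In light vs control, 1416 isotigs were at least 2-fold higher and 1316 at least 2-fold lower. Simulated unchanged libraries gave on average 1117 higher and 1043 lower, and at most 2274 together, so counting error alone would give most of this number. The counting interval excluded 1 for 410 of the higher and 355 of the lower isotigs, against 255 of both kinds together in the simulations. Of the 2430 tested isotigs with a mean of at least 100 reads, 16 were at least 2-fold higher and 24 lower, and the standard deviation of their log2 ratios was 0.38.

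The named isotigs with the highest ratios rested on few control reads. A DNA fragmentation factor isotig (isotig25684) had 0 reads in control and 26 after strong light, at least 6.26-fold higher. An endothelial-specific receptor tyrosine kinase isotig (isotig07418) had 0 and 63 reads, at least 15.8-fold higher. A nectin-like isotig named poliovirus receptor-related protein (isotig00256) had 0 and 20 reads, at least 4.71-fold higher. An isotig of ribosomal protein L44e (isotig03879) had 0 and 12 reads, at least 2.65-fold higher. Isotigs named elongation of very long chain fatty acids protein 4 (isotig19213; 18.1-fold, 2.88 to 754), phosphatidylinositol-4-phosphate 3-kinase (isotig23287; 13.4-fold, 2.03 to 565) and von Willebrand factor (isotig29302; 12.4-fold, 1.86 to 527) had 1 control read each. The other 5 isotigs on this side were named tenascin, carboxypeptidase N regulatory subunit, angiopoietin 1, tripartite motif-containing protein 56 and a telomere elongation helicase, with 1 to 3 control reads and 8 to 23 reads after strong light.

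On the lower side, a thyroglobulin-domain isotig (isotig21096) had 283 reads in control, 22 in the dark and 5 after strong light. It was 59.3-fold lower after strong light (25.1 to 184). An alpha-2-macroglobulin isotig (isotig16383), named for a protease inhibitor of body fluids, had 93 control reads and 6 after strong light, 16.2-fold lower (7.18 to 45.4). A ficolin isotig (isotig06210), of the fibrinogen-related lectins, was 32.5-fold lower (5.41 to 1323), and a tenascin isotig (isotig27274) was 11.9-fold lower (5.80 to 28.4). A peptidylglycine monooxygenase isotig (isotig25773), named for an enzyme that amidates neuropeptides, was 7.16-fold lower (3.02 to 20.6), and one of ATP synthase subunit e (isotig02009) was 9.17-fold lower (3.28 to 35.5). A second tripartite motif isotig (isotig19579) had 19 reads in control and 0 after strong light, at least 4.89-fold lower. The other 5 were named cytochrome P450, RNA polymerase III subunit, ribosomal protein L10Ae, uridine monophosphate synthetase and serine/arginine repetitive matrix protein, with 5 to 11 control reads and at most 1 after strong light; for the P450 isotig (isotig08382) and the matrix protein isotig (isotig26142) the difference was not detectable at this depth. Of the 24 isotigs, 22 shared their KEGG orthology with other isotigs, and summed over each orthology only 3 of them remained at least 2-fold apart in the same direction. Thus most of these differences held for an isotig and not for the orthology as a whole.

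Most fixed lists did not stand apart after strong light. The phototransduction list had 42 tested members, none of them named opsin or rhodopsin. It was built from name patterns and took in families not particular to light detection, such as G protein alpha-12, TRPA1, TRPC4 and TRPM2 isotigs. The list is therefore not a test of phototransduction as such. Its median log2 ratio was 0.00 (interval -0.22 to 0.37), with 4 members at least 2-fold higher and 3 lower, among them a retinol dehydrogenase 12 isotig (isotig20460) that was 4.01-fold higher (1.47 to 13.6). The circadian clock and photolyase list (16 members, median 0.03) had 1 member higher, an isotig of nuclear receptor subfamily 1 group D (isotig13977; 2.25-fold, 1.24 to 4.23), and 2 lower, which rested on at most 3 control reads. The heat shock and chaperone list (56 members, median 0.04) had 1 higher and 3 lower. The abundant chaperone named heat shock protein 90kDa beta (isotig13076) had 3593 reads in control and 3356 after strong light. The antioxidant list had a median of 0.14 (0.06 to 0.22) over 49 members, at percentile 94.8 of matched random lists, with 2 members higher and 1 lower. DNA repair (34 members, median 0.06), apoptosis (28, 0.02), cell cycle (30, -0.02), nervous system (43, -0.14), muscle (111, 0.02), digestion (39, 0.02) and ribosomal proteins (87, -0.04) lay between percentiles 4.33 and 66.6. The pigment list had 3 tested members, with log2 ratios of 0.67, -0.21 and -0.46. They were D-dopachrome decarboxylase (isotig14943), astacin (isotig07422), which is named for a protease, and microphthalmia-associated transcription factor (isotig08827). The 2 transcripts of the mitochondrial genome list, cytochrome c oxidase subunit 1 (isotig07060) and ATP synthase subunit a (isotig12529), had log2 ratios of -0.07 and -0.06.

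The immune and coelomocyte list was the only one of the 15 lists in the outer percentiles after strong light, where random lists would give 0.75. Its median was -0.10 (-0.26 to -0.01), at percentile 1.69. It had 4 members at least 2-fold higher and 11 lower, while 64 were within 2-fold. A C-type mannose receptor isotig (isotig22072) was 2.15-fold lower (1.92 to 2.40), a complement component 4 isotig (isotig21847) 2.03-fold lower (1.63 to 2.54) and a galectin-9 isotig (isotig07141) 2.68-fold lower (1.47 to 5.12). The neighbouring galectin-9 isotig (isotig07140) had 116 reads in control and 212 after strong light, and summed over its orthology galectin-9 had a log2 ratio of 0.46. The sums for the mannose receptor (isotig22072) and complement component 4 (isotig21847) orthologies had log2 ratios of -0.15 and -0.19. A complement component 4 binding protein isotig (isotig06225) was 2.64-fold higher (1.95 to 3.62). The collagen and extracellular matrix list (75 members, median 0.03, percentile 73.8) had 10 lower members, of which 7 were tenascin isotigs, and 5 higher ones, of which 2 were tenascin isotigs and 1 was collagen type XVIII (isotig18183; 2.30-fold, 1.55 to 3.47). The most abundant fibrillar collagen isotig (isotig20045) was 1.12-fold higher (1.09 to 1.14), a difference within 1.5-fold.

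The dark library differed more from control than the light library did. Ribosomal protein transcripts and 2 mitochondrial transcripts took a larger part of the dark library. On the low side, muscle was the only list whose 95% interval lay wholly below the median of all isotigs. Ribosomal proteins made up 12.8% of reads in the dark library (95% Wilson interval 12.7 to 12.8), 8.02% in control (7.98 to 8.06) and 7.84% in the light library (7.80 to 7.88). The 2 mitochondrial transcripts made up 0.845% (0.831 to 0.859), 0.498% (0.488 to 0.510) and 0.476% (0.465 to 0.486). The 3 most abundant isotigs (isotig24195, isotig22175 and isotig10678), all without a name, made up 12.4%, 7.17% and 6.39%.

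**Figure D1:**
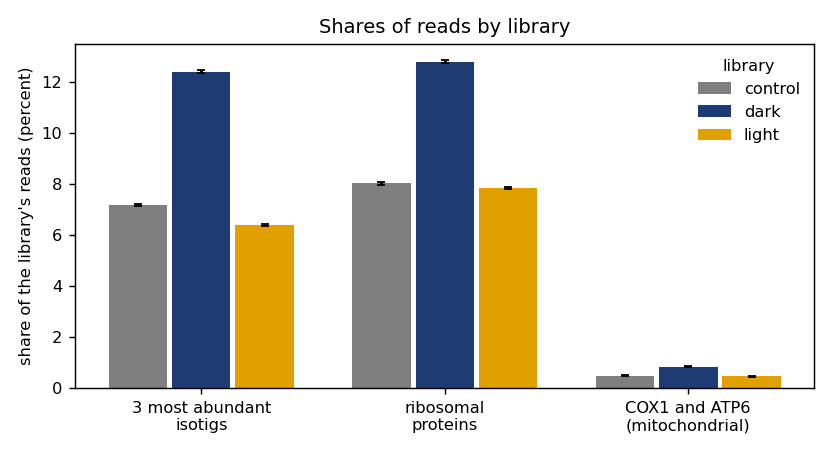
Share of each library's reads, in percent, taken by the 3 most abundant isotigs, by ribosomal protein isotigs and by the 2 mitochondrial transcripts, for the control, dark and light libraries; error bars are 95% Wilson intervals and cover counting error only. The dark library has the highest share in each set, 12.4%, 12.8% and 0.845%.

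In dark vs control, 1292 isotigs were at least 2-fold higher and 4380 lower, with a median log2 ratio of -0.31. The counting interval excluded 1 for 469 of the higher and 2572 of the lower, against 238 together in simulated unchanged libraries. Part of this split follows from scaling to the library total. With median-of-ratios size factors, which move the median to 0.00, 2184 isotigs were higher and 2995 lower, so that the share of higher isotigs went from 22.8% to 42.2%; TMM factors gave 2122 and 3034. Dark list medians are therefore given below on the deposited scale and relative to the median of all tested isotigs. Of the isotigs with a mean of at least 100 reads, 50 were higher and 358 lower, and the standard deviation of their log2 ratios was 0.72.

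The 87 ribosomal protein isotigs had a median log2 ratio of 0.70 (0.68 to 0.73), 1.01 above that of all isotigs, and 86 of them lay above it. This was at percentile 100 of random lists matched on expression, whose median was -0.05. On the deposited scale 2 members were at least 2-fold higher and 1 lower, and with size factors 49 were higher and 1 lower. The isotig of L13e (isotig20778) had 3630 reads in control, 6938 in the dark and 3857 after strong light, 1.77-fold higher in the dark (1.70 to 1.84). Cytochrome c oxidase subunit 1 (isotig07060) was 1.73-fold higher (1.67 to 1.80) and ATP synthase subunit a (isotig12529) 1.64-fold higher (1.58 to 1.72).

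**Figure D2:**
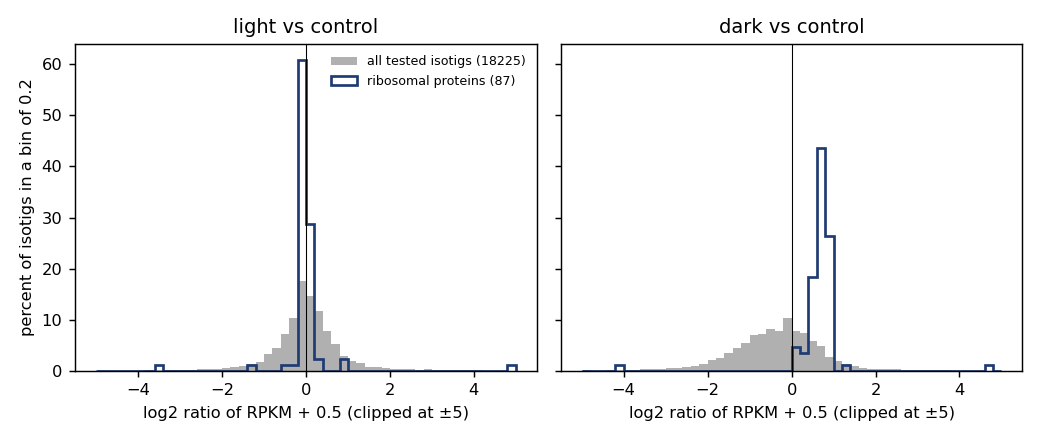
Distribution of log2 ratios (horizontal axis, RPKM plus 0.5, clipped at 5 on both sides) as the percent of isotigs per bin (vertical axis) for all 18225 tested isotigs in grey and the 87 ribosomal protein isotigs as a line. After strong light both sets centre near 0, with medians of 0.00 and -0.04, and in the dark the medians are -0.31 and 0.70.

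The muscle list had the lowest median of the large lists in the dark, -0.66 (-0.87 to -0.51), which was 0.35 below all isotigs and at percentile 0.180. The random lists behind this percentile hold named and unnamed isotigs. Broad annotation terms were also low in the dark. Relative to all isotigs of at least 5 RPKM, binding (388 isotigs) had -0.31 and protein binding (250 isotigs) -0.40. The percentiles of the muscle, matrix and immune lists thus do not separate these genes from annotated isotigs in general. Of its 111 members 38 were at least 2-fold lower and 5 higher, or 24 and 5 with size factors. The lower members included myosins that carry cargo or shape the cell cortex and are not sarcomere proteins. These were myosin VI (isotig16090, 5.16-fold lower, 2.81 to 10.2), myosin X (isotig18746, 2.94-fold, 1.97 to 4.46) and myosin I (isotig17115, 2.73-fold, 1.94 to 3.89), among others not counted here. Among sarcomere genes, a troponin I isotig (isotig17039) had a log2 ratio of -1.50, with 25 control and 9 dark reads, while a titin isotig (isotig01193) was 3.80-fold higher (1.80 to 8.96) although its orthology as a sum had a log2 ratio of -0.14.

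The collagen and extracellular matrix list had a median of -0.57 (-0.82 to -0.19), 0.26 below all isotigs and at percentile 0.390. Relative to all isotigs its interval was -0.51 to 0.12, which spans their median. Of 75 members 22 were lower and 5 higher, or 17 and 10 with size factors. Basement membrane genes were among the lower ones. Laminin gamma 1 (isotig18221) was 5.26-fold lower (2.99 to 9.88), and 2 collagen type IV isotigs (isotig19048 and isotig10619) were 2.70-fold (2.20 to 3.32) and 2.81-fold lower (2.26 to 3.52). Chondroitin sulfate proteoglycan 4 (isotig08961) was 3.28-fold lower (2.88 to 3.74), and the collagenase MMP-13 (isotig24202) 2.81-fold lower (2.31 to 3.44). A tenascin isotig (isotig19241) was 2.76-fold higher (2.46 to 3.09) and one named neurocan (isotig10750) 3.80-fold higher (3.07 to 4.74). The most abundant fibrillar collagen isotig (isotig20045) had a log2 ratio of -0.18, which was 0.14 with size factors, so its direction depends on the scaling.

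The immune and coelomocyte list had a median of -0.51 (-0.71 to -0.10), 0.20 below all isotigs and at percentile 2.14. Relative to all isotigs its interval was -0.40 to 0.21, which spans their median. Of its 79 members 19 were lower and 4 higher, or 14 and 11 with size factors. Of all 18225 tested isotigs 4380 were lower and 1292 higher, or 2995 and 2184 with size factors. The share of lower members was thus close to that of all isotigs, and the members named next do not mark the list. Complement factor I (isotig14834) was 8.38-fold lower (2.96 to 32.7), a macrophage scavenger receptor (isotig28258) 4.58-fold lower (2.47 to 9.13), the NF-kappa-B p105 subunit (isotig09713) 3.16-fold lower (1.65 to 6.47) and complement factor H (isotig23867) 2.87-fold lower (2.25 to 3.69). Among members whose counting interval excluded 1, the medians of this list and of the matrix list lay 0.23 and 0.18 above, not below, those of all such isotigs.

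No other list was in the outer percentiles in the dark. The counts of members below stand beside 4380 lower and 1292 higher of all 18225 tested isotigs, or 2995 and 2184 with size factors. For the phototransduction list the share of lower members was close to that of all isotigs. The heat shock and chaperone list (median -0.52, 0.21 below all isotigs, percentile 6.71) had 16 lower members, most of them DnaJ co-chaperones such as DnaJ subfamily C member 7 (isotig10285; 5.14-fold lower, 1.71 to 20.8), and 2 higher, or 11 and 2 with size factors. The phototransduction list (median -0.42, relative -0.11) had 10 lower members and 1 higher, or 6 and 2 with size factors, among the lower ones a G protein alpha-12 subunit (isotig15155; 3.16-fold, 2.28 to 4.45) and a TRPM2 channel (isotig26803; log2 ratio -1.71). The clock list (median -0.20, relative 0.11) had 5 lower, with casein kinase 1 gamma (isotig10165) 3.01-fold lower (2.37 to 3.84), and 1 higher, a photolyase isotig (isotig18878) with 3 control and 8 dark reads; with size factors 2 were lower and 4 higher. The antioxidant list (median -0.22, relative 0.09) had 6 higher and 9 lower, but 7 and 4 with size factors, with thioredoxin 1 (isotig10271) 2.12-fold higher (1.43 to 3.19) and thioredoxin reductase (isotig17891) at a log2 ratio of -1.27. The nervous system list (median -0.52, relative -0.21) had 3 higher and 12 lower, or 3 and 9 with size factors, among them syntaxin 1A (isotig17787), a protein of synaptic vesicle fusion, 3.97-fold lower (2.79 to 5.79). The apoptosis list (median -0.57, relative -0.26) had 2 higher and 7 lower, but 4 and 3 with size factors, among the lower ones BCL-W (isotig17264; 3.44-fold, 1.71 to 7.51). The DNA repair list (median -0.56, relative -0.25) had 0 higher and 6 lower, or 2 and 5 with size factors, among them XPA (isotig13154; log2 ratio -1.47), a nucleotide excision repair protein. The cell cycle list (median -0.22, relative 0.09) had 5 higher, among them a histone H1/5 isotig (isotig22036; 4.54-fold, 3.91 to 5.30), and 6 lower, among them DNA topoisomerase II (isotig16672; log2 ratio -2.24); with size factors 7 were higher and 4 lower. Thus the balance of the clock, antioxidant, apoptosis and cell cycle lists depends on the scaling. The digestion list (39 members), which holds markers of the tissue in the source label, had a median of -0.33 (relative -0.02, percentile 42.5), with 3 higher and 14 lower, or 3 and 8 with size factors. In the pigment list, microphthalmia-associated transcription factor (isotig08827), a regulator of pigment cells in vertebrates, had 15 reads in control, 2 in the dark and 11 after strong light, 8.11-fold lower in the dark (1.89 to 73.1).

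**Figure D3:**
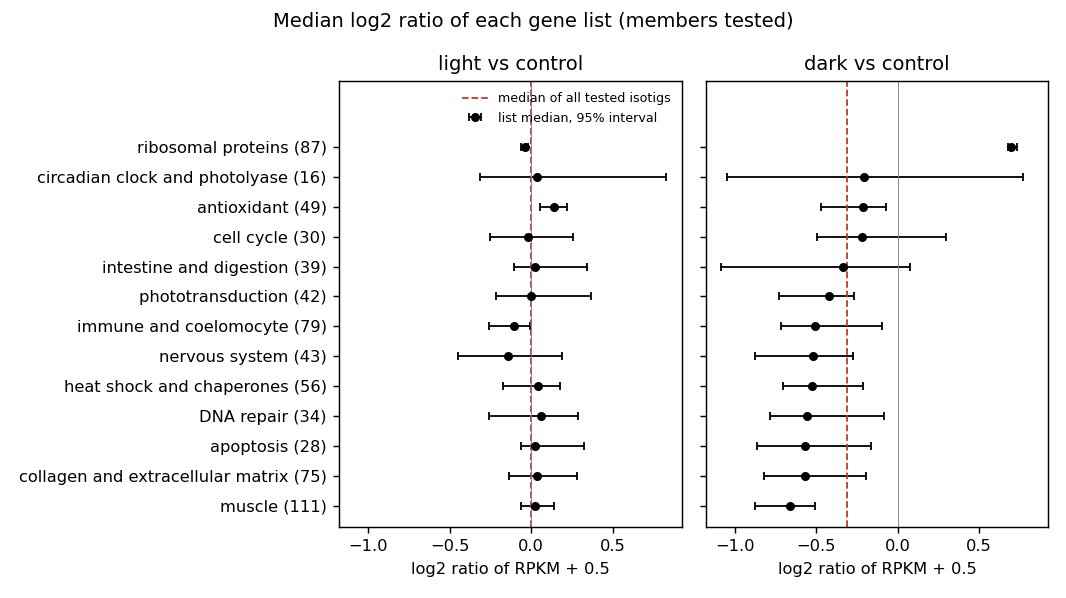
Median log2 ratio (horizontal axis, RPKM plus 0.5) of each fixed gene list with at least 6 tested members (number in brackets), for light vs control on the left and dark vs control on the right; bars are order-statistic 95% intervals of the median and the dashed line is the median of all tested isotigs. In the dark the ribosomal protein list lies at 0.70 and the muscle list at -0.66, around an overall median of -0.31.

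Of the 12 named isotigs with the lowest dark ratios, 11 had 0 dark reads, with 5 to 13 control reads. The best counted of these were named adenomatosis polyposis coli protein (isotig23130, at least 3.30-fold lower), tyrosine kinase receptor 1 (isotig11661, at least 3.01-fold) and a kinesin family member (isotig22505, at least 2.42-fold). The others were named molybdenum cofactor biosynthesis protein, ubiquitin carboxyl-terminal hydrolase, the ubiquitin ligase MYCBP2, Notch, a lysosomal-enzyme N-acetylglucosamine transferase, PDS5, a JmjC histone demethylase and a telomere elongation helicase. Their smallest folds in the counting interval lay between 0.991 for the transferase and 2.42 for the helicase. For the transferase, with 5 control reads, the difference was not detectable at this depth. The alpha-2-macroglobulin isotig (isotig16383) was also lower in the dark, 25.1-fold (9.50 to 94.2). Among the 12 highest, a ficolin isotig (isotig24848) had 54 reads in control and 375 in the dark, 6.42-fold higher (4.82 to 8.71). A chondroadherin isotig (isotig02350) was 6.93-fold higher (3.30 to 16.8), although its orthology as a sum had a log2 ratio of 0.04. The neighbouring chondroadherin isotig (isotig02349) had 108 reads in control and 40 in the dark. A dynactin 5 isotig (isotig09020) was 12.5-fold higher (3.14 to 108), with a log2 ratio of 0.79 for its orthology as a sum. An isotig named ATP synthase subunit 6 (isotig03824), of another orthology than subunit a (isotig12529), was 5.09-fold higher (2.10 to 14.8). A P2X purinergic receptor isotig (isotig27495; 11.1-fold, 1.64 to 474) and a tenascin isotig (isotig29551; 14.8-fold, 2.30 to 620) had 1 control read, and the fragmentation factor, L44e and poliovirus receptor-related isotigs had 0. The rest were the histone H1/5 isotig (isotig22036) given above, a second ficolin isotig (isotig03192, 6.47-fold, 1.93 to 33.9) and a phosphatase of phosphatidylinositol trisphosphate (isotig23515, 7.40-fold, 0.992 to 328). The difference of the phosphatase was not detectable at this depth. Summed over their KEGG orthology, 8 of the 21 that shared one with other isotigs remained at least 2-fold apart in the same direction.

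Large differences on firm counts were also looked for after the values had been seen, among named isotigs with a mean of at least 100 reads. An apolipoprotein B isotig (isotig13070), named for the backbone protein of lipid particles, had 5279 reads in control, 1141 in the dark and 6730 after strong light, a log2 ratio of -2.32 in the dark, and a second one (isotig14922) was 4.52-fold lower (3.67 to 5.62). A von Willebrand factor isotig (isotig17502) was 3.91-fold lower (3.68 to 4.16), integrin beta 1 (isotig10927), a receptor for extracellular matrix, 5.19-fold lower (3.68 to 7.49), a thrombospondin isotig (isotig03731) 5.99-fold lower (4.28 to 8.57), dual oxidase (isotig10117), which makes hydrogen peroxide, 6.90-fold lower (4.34 to 11.5), and an isotig named epidermal growth factor (isotig29479) 9.86-fold lower (8.07 to 12.2). The most read isotig with a name, melanoma-associated antigen p97 (isotig13120), of the transferrin family, had 60978 reads in control, 30465 in the dark and 72889 after strong light. It was 2.16-fold lower in the dark (2.14 to 2.19). Its log2 ratio of -1.11 became -0.80 with size factors, which is below 2-fold, so the size of this difference depends on the scaling.

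The light and dark libraries, which received opposite treatments and share no control, differed most. In light vs dark, 4769 isotigs were at least 2-fold higher and 1474 lower, with a median log2 ratio of 0.32; size factors gave 3332 and 2587. Ribosomal proteins had a median of -0.73 (-0.78 to -0.69), 1.05 below all isotigs, and muscle genes a median of 0.67 (0.47 to 0.89), 0.35 above. The other lists lay between percentiles 4.84 and 96.9 of matched random lists. The highest of these was phototransduction, with a median of 0.74 (0.42 to 0.84). Relative to all isotigs this was 0.41 (0.09 to 0.52), an interval wholly above their median. Of its 42 members 11 were higher and 3 lower, or 8 and 4 with size factors, a share of higher members close to that of all isotigs. As stated above, this list is not a test of phototransduction as such. An isotig of Notch (isotig25006), a receptor for signals between cells, had 20 reads after strong light and 0 in the dark, at least 5.10-fold higher. One of ribosomal protein L8e (isotig08005) was at least 5.94-fold higher, and one of MYCBP2 (isotig28137) at least 2.04-fold higher. On the lower side stood isotigs named L10Ae (isotig10422, at least 3.47-fold lower), tenascin (isotig16485, 16.7-fold lower, 6.87 to 52.6) and RNA polymerase III subunit (isotig27391). The last had 4 dark reads and 0 after strong light, a difference not detectable at this depth. Summed over its orthology only MYCBP2 remained at least 2-fold apart in the same direction, and the sums for Notch (-0.44) and L8e (-0.61) had the opposite sign.

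The ratios of light and of dark to control shared many isotigs, but both use the same control library. In both, 550 isotigs were at least 2-fold higher, against 100 for independent lists of these sizes and 609 in simulated unchanged libraries with a shared control. In both, 517 were lower, against 316 and 277. Opposite directions were seen for 171 isotigs higher after strong light and lower in the dark and for 56 the other way, against 340 and 93.3 for independent lists. The correlation across isotigs, which are not independent replicates, was 0.31, and 0.52 in the simulations. The covariance was 0.296, against 0.299 from the shared control alone, a difference of -0.003. The control library cannot be split. In the simulations the shared control alone gave more isotigs higher in both than were observed. The 517 lower in both exceeded the simulated 277. The simulations lack the shift of the dark library to lower ratios, which would lower the first count and raise the second. The source of either overlap, beyond the shared control, was therefore not resolved.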

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

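All tests reported in this part were chosen after the result was seen. Among named isotigs with a mean of at least 5 RPKM, 8 were at least 2-fold apart from control in opposite directions in the light and dark libraries, with both counting intervals clear of 1. This set is given on the deposited scale only. Size factors raise the dark ratios, so membership near the 2-fold limit, such as that of isotig20477, depends on the scaling. The difference between the 2 effects was not tested, since each rests on 1 library, and both share the control. Lysosomal-associated membrane protein (isotig13012) had 369 reads in control, 79 in the dark and 968 after strong light, with log2 ratios to control of 1.32 in light and -2.33 in the dark. Nidogen (isotig22631), a basement membrane protein, had log2 ratios of 1.02 in light and -1.90 in the dark. Collagen type XVIII (isotig18183), also of basement membranes, had 1.18 and -2.06. Chordin (isotig19016), an antagonist of bone morphogenetic proteins, had 1.33 and -1.33. The poly(A)-specific ribonuclease subunit (isotig20477) had 1.10 and -1.07, and RNA-binding protein 25 (isotig01637) had 1.09 and -1.47. The other 2 moved the opposite way, a tenascin isotig (isotig16485) with -2.45 in light and 1.38 in the dark, and a subunit of respiratory complex I (isotig02671) with -1.53 and 1.05.

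The ribosomal protein pattern of the dark library was weighed against technical explanations. Abundant isotigs that take reads from all others lower these by 1 common factor, which may account for part of the overall median of -0.31 (-0.23 without the 20 most abundant isotigs), but such a factor leaves no gap between isotigs, and ribosomal proteins lay 1.01 above all isotigs (0.99 to 1.04). Matching on length and expression argues against isotig length as the whole cause too, since the list median stood at percentile 100 among such lists. The gap to the median of such lists was 0.81, smaller than the gap to all isotigs. Expression was matched only in bins, so a shift shared by abundant isotigs was not tested. Among the 20 most abundant isotigs, some unnamed ones were also higher in the dark, such as isotig24195 (log2 ratio 0.72) and isotig22175 (0.94). Others were lower, such as isotig13120 (-1.11) and isotig28665 (-1.15), so this question stays open. RNA breakdown with reads kept near the 3' end cannot be told apart from the treatment: isotigs of at least 1500 bases with similar RPKM in both libraries were covered over a similar part for their reads in dark and control (difference -0.125 percentage points, -0.422 to 0.110, 742 isotigs), but these leave out the isotigs that were lower, and choosing isotigs lower in 1 library gave a positive difference in 6 of 6 directed pairs of libraries. A difference between animals or library preparations cannot be told apart from the light, because there is 1 dark library; GC content was not tested without isotig sequences, and a change in the cells or in transcription with darkness remains an untested hypothesis.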

How the results depend on the processing

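The summed orthologies, the filter on control and light alone and the list names as first written were chosen after seeing the data. Total counts of isotigs at least 2-fold apart stayed within 1.5 times under size factors, TMM factors, totals without the 20 most abundant isotigs and both other pseudocounts, in all 3 comparisons and in the overlap. The other settings keep fewer or more isotigs by construction. Light vs control gave 4316 isotigs without a filter, 1185 at a mean of 5 RPKM, 643 at a mean of 10 reads, 5785 at 1.5-fold, 796 at 4-fold, 765 with counting intervals clear of 1 and 1761 with a minimum isotig length. Dark vs control gave 3727, 2858, 9796, 1464 and 3041 at 5 RPKM, 10 reads, 1.5-fold, 4-fold and clear intervals. Light vs dark gave 3305, 10415, 1795 and 3657 at 10 reads, 1.5-fold, 4-fold and clear intervals. The overlap gave 1811, 375, 166, 2511, 267, 172 and 663 in the order of light vs control, and the correlation 0.21 at 5 RPKM and 0.13 at 10 reads. Relative to all isotigs, the ribosomal protein median in the dark was 0.95 without a filter, 0.98 at 10 reads and 1.65 with clear intervals, and the immune median in the dark was -0.43 with the names as first written. With clear intervals the immune median was -0.56 in light and reversed to 0.23 in the dark, and the matrix median in the dark reversed to 0.18; this setting leaves out isotigs near a ratio of 1, and the cause was not tested further. Summing over one KEGG orthology reversed 11 of 49 ratios of named isotigs, left 22 outside their counting interval and 16 inside. In light vs control the reversed ones became -0.0370 (isotig03879), -0.38 (isotig29302), -0.0850 (isotig29551), 0.0546 (isotig19579), 0.0782 (isotig06210) and 0.0645 (isotig10422). In dark vs control they became -0.44 (isotig23515), 0.55 (isotig25006) and 0.84 (isotig11661), and in light vs dark -0.44 (isotig25006) and -0.61 (isotig08005). Size factors and TMM factors each moved 1 of the 54 ratios of named isotigs outside its interval and reversed 0. No paired analysis was possible because each group has 1 library. With a median of 18 reads per tested isotig, depth limits single ratios.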

Other observations

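All tests in this part were chosen after the data had been seen. Beyond the fixed lists, 322 gene ontology terms and KEGG names with at least 12 isotigs were scanned for medians in the outer percentiles of 2000 matched random sets. Sets drawn at random would give 16.1. The random sets came from all 13795 scanned isotigs, with or without annotation, so 16.1 is not the number that chance gives for annotated sets. In the dark, 129 terms lay on the low side and 14 on the high side; terms overlap and are not independent. Terms of signalling and membrane traffic were among the lowest. Broad terms were low as well, such as membrane (277 isotigs, relative -0.51) and binding (388 isotigs, relative -0.31). Medians of log2 ratios are given with the value relative to all scanned isotigs in brackets. Protein kinase activity had -1.13 (-0.82), with 47 of 74 isotigs at least 2-fold lower on the deposited scale, small GTPase mediated signal transduction -1.17 (-0.87), with 14 of 19, cell surface receptor signaling pathway -1.08 (-0.78), with 21 of 35, and cell-substrate adherens junction -1.16 (-0.85), with 10 of 19. On the high side stood the large ribosomal subunit, 0.71 (1.02), ATP biosynthetic process, 0.66 (0.97), the mitochondrial respiratory chain, 0.39 (0.70), and, at percentile 99.4, isotigs named ficolin, 0.01 (0.32), of which 11 were higher and 7 lower. After strong light, 3 terms lay on the low side and 24 on the high side, with smaller shifts. Organ morphogenesis (0.35, 29 isotigs) and cell adhesion (0.35, 18 isotigs) had the highest medians, and tRNA aminoacylation had a median of -0.19 over 25 isotigs.

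Some isotigs of the same name and neighbouring number moved in opposite directions. Of 114 such pairs with a mean of at least 20 reads each, 11 did so in light vs control and 14 in dark vs control with both counting intervals clear of 1. In all of these the summed reads of the pair stayed within 1.5-fold. Choosing pairs by opposite directions itself holds their sums near no change, so these sums cannot show that reads were traded. In elongation factor 2 (isotig05178 and isotig05179) the first isotig held most of the change, with 546 and 72 reads in control and 830 and 53 in the dark. Cytochrome c oxidase subunit 5a (isotig09535 and isotig09536) had 190 and 86 reads in control but 81 and 243 after strong light, with sums of 276 and 324. Peroxiredoxin 6 (isotig05339 and isotig05340) had 27 and 15 reads in control but 3 and 41 in the dark, with sums of 42 and 44. Translation initiation factor 1 (isotig07174 and isotig07175) had 107 and 80 reads in control, and its second isotig had 163 in the dark and 122 after strong light, with sums of 187, 190 and 191.

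Isotigs 16-fold or more apart between libraries numbered 122 at a mean of at least 5 RPKM, 72 of them with 0 reads in the dark library. Counting noise alone gave 25.0 on average and at most 41 in 100 simulated sets of unchanged libraries, so that it may account for part of them. Reads divided between isotigs of one gene or gene family are a candidate explanation for another part: of the 28 with another isotig of the same KEGG orthology, 46.4% stayed at least 2-fold apart when summed, which leaves this open. Splice forms, alleles of different animals and a response to light cannot be told apart here, because each group has 1 library and isotig sequences were not analysed. An unnamed isotig (isotig28282) had 0 reads in control, 169 in the dark and 116 after strong light, and another (isotig26603) had 66 reads after strong light and 0 in both other libraries.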
